A study of Mus musculus with 12 samples.

How the data were processed

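Bulk RNA-seq was available for 12 libraries of haematopoietic stem cells (HSCs) from C57BL/6 mouse bone marrow, 3 in each of 4 groups: wild type (WT) and *Bst2* knockout (KO), each naive or from mice given recombinant interferon-γ (IFN-γ, 100 µg) for 24 h. Per the labels, HSCs were sorted from bone marrow as lineage-negative, c-Kit-positive, CD150-positive cells lacking CD48 and CD34, and a stranded total RNA kit (Takara SMARTer) was used. The cells were sorted from each mouse, but the labels do not tie libraries to mice, so the p-values measure the spread between these libraries. Each title carries a library code from 1 of 3 code series, FL-06 (6 libraries), R-09 (4 libraries) and R-07 (2 libraries, KO samples only). What a code series stands for is not stated.

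The authors deposited 1 table of normalized values per gene, a never-negative signal made from read counts, and a second table that holds the identical values in another order. STAR and DESeq are named in the submitters' processing notes, without versions or roles. The genome build, the annotation and the handling of strand are not given in the sources used here, so no coordinates are printed, and genes with near-identical copies are uncertain. The deposited values were not whole reads. Low values in each library clustered at steps of a size typical of that library, but only 2.28 to 4.60% of its values were whole multiples of the step (tolerance 0.01), so reads were not recovered and no count model was used. From the step and the total, the depth was estimated at 0.495 M reads for WT naive 2 and at 8.76 to 52.1 M reads for the other 11 libraries. At 1 read per step, 3 reads would be worth 102 units in WT naive 2 and 1.02 to 5.22 units elsewhere. In each library the lowest value above 0 lay below the step (15.5 against 33.8 units in WT naive 2). That a step is 1 read was therefore not shown, and the depths are rough. The normalized totals lay between 13.8 and 17.7 M units.

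Of 24972 rows, 26 had names turned into dates and were left out, which left 24946. The planned test for counts did not apply to this unit, and the limma-trend fallback written for normalized values was used. Values were analysed as log2(value + 1), and fold changes on this scale understate the change of low genes. Genes with a value of at least 100 in at least 3 libraries were tested (10816 genes). The minimum of 100 was set once the unit was known and before any test was fitted. All 12 libraries entered 1 linear model with 4 group means and the code series as a covariate (limma 3.58.1 in R 4.3.3, empirical Bayes with a trend, residual df 6, prior df 5.02). The comparisons were the IFN-γ effect in WT, the IFN-γ effect in KO, the genotype difference in naive and in treated HSCs, and the difference between the IFN-γ effects (interaction). The IFN-γ effect averaged over both genotypes was added after the data were seen. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. The IFN-γ effects in WT and KO share no libraries. *Bst2* was also compared between genotypes by a two-sided exact permutation test of the means, added after the data were seen.

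Before the data were examined, 30 gene lists were fixed, of which 29 had at least 3 tested members. The mitochondrially encoded list had 0 of its 15 genes in the table. The lists were IFN-γ response, type I interferon-stimulated genes, MHC class I and class II presentation, IFN-γ receptor and signalling, HSC identity, niche adhesion and homing, G1/S and G2/M cell cycle, quiescence and CDK inhibitors, MYC and ribosome biogenesis, NF-κB targets, p53 targets, apoptosis, immediate early genes, myeloid, megakaryocyte and lymphoid priming, erythroid genes, markers of mature B and plasma cells, T and NK cells, neutrophils, monocytes with macrophages and dendritic cells, mast cells and basophils, endothelium and stroma, oxidative phosphorylation, glycolysis, replication-dependent histones and the neighbours of *Bst2*. Some genes belong to more than 1 list. Each list was tested against all other genes with camera (preset correlation 0.01, and again with an estimated correlation), and fry was run on the same lists. Adjusted p-values of lists are from camera with the preset correlation unless stated otherwise, adjusted over the 29 lists of a comparison. List members past the threshold are also counted adjusted over the list alone. A permutation of treatment labels within genotype and code series was added after the data were seen. It used the mean log2 value of a list per library, over all 96 arrangements.

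The rule for named genes took *Bst2*, the 10 largest rises and falls among genes past the threshold with a mean log2 value of at least 7 and no overlap between the groups, up to 4 members of each list past the threshold or otherwise the 2 with the highest mean, and the gate genes *Kit*, *Slamf1*, *Cd48* and *Cd34*. The expression minimum was written for log2 CPM and carried over to this scale. Genes named from the adjustment over a list alone, and other genes outside this rule, were chosen after their values were seen.

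The model was tested on simulated data with 200 changed genes in 5 simulations. Of genes changed 2-fold it recovered 23.6% for the effect in WT, 26.0% for that in KO, 20.2% for the naive genotype difference and 22.0% for the treated genotype difference. Of genes changed 4-fold it recovered 61.6%, 62.4%, 56.6% and 58.8% in the same order. Calls outside the 200 changed genes numbered 34, 17, 28 and 16 over the 5 simulations, in the same order. These calls may include members of the planted list described next. The interaction and the average over both genotypes were not simulated. A planted list of 30 genes shifted by 0.5 was found in 5 of 5 simulations for each of these comparisons. The simulated genes varied independently, and the planted list was tested alone with the preset correlation, at an unadjusted camera p below 0.05. The simulation therefore does not show how the list tests perform on correlated genes.

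Alternatives fixed in advance were pseudocounts of 0.1 and 10, no filter, a CPM of at least 1 in 3 libraries, fits without the code series, with the replicate number as a block, or with only the groups compared, and leaving out each library in turn. Quantile normalization, rescaling by median ratios or without non-coding and haemoglobin genes, library weights, leaving out the R-09 series and a minimum of 100 in all 12 libraries were added after the data were seen. Transcript lengths came from GENCODE M21. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.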

Results

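Gene expression was measured in sorted mouse HSCs, the rare bone marrow cells that give rise to all blood lineages. WT and *Bst2* KO mice were compared, each without treatment or 24 h after IFN-γ, a cytokine that induces antigen presentation and antiviral genes. *Bst2* encodes tetherin, an interferon-induced membrane protein. Each of the 4 groups held 3 libraries. The estimated depth was 8.76 to 52.1 M reads in 11 libraries and 0.495 M reads in WT naive 2. WT naive 2 also had the fewest genes above 0 (10567, against 12395 to 14640 in the others). If 1 step is 1 read, a value listed at 0 there says little about genes below about 102 units, the worth of 3 reads. The values are deposited normalized counts, called units here.

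*Bst2* separated the genotypes in all 12 libraries. It lay between 152 and 1514 units in the 6 WT libraries (mean 754 ± 558, SD, n = 6) and between 0 and 24.8 units in the 6 KO libraries (mean 9.35 ± 10.3, SD, n = 6). The ratio of the means was 80.6, and a two-sided exact permutation test of the 924 arrangements gave p = 0.002165. KO naive 3 and KO IFN-γ 3 were listed at 0. Within WT, *Bst2* averaged 618 ± 655 units in naive and 889 ± 542 units in treated HSCs (SD, n = 3 each). The limma difference did not pass the threshold (log2 fold change 0.95, SE 1.30, adjusted p = 0.82). This SE pools all 12 libraries, including KO values near 0, so the test says little about *Bst2* in WT. In FL-06 the naive WT libraries had 336 and 152 units and the treated ones 547 and 606. In R-09 the values were 1367 in naive and 1514 in treated WT. Without the R-09 libraries the ratio between genotypes was 48.7 (exact permutation p = 0.02857).

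**Figure D1:**
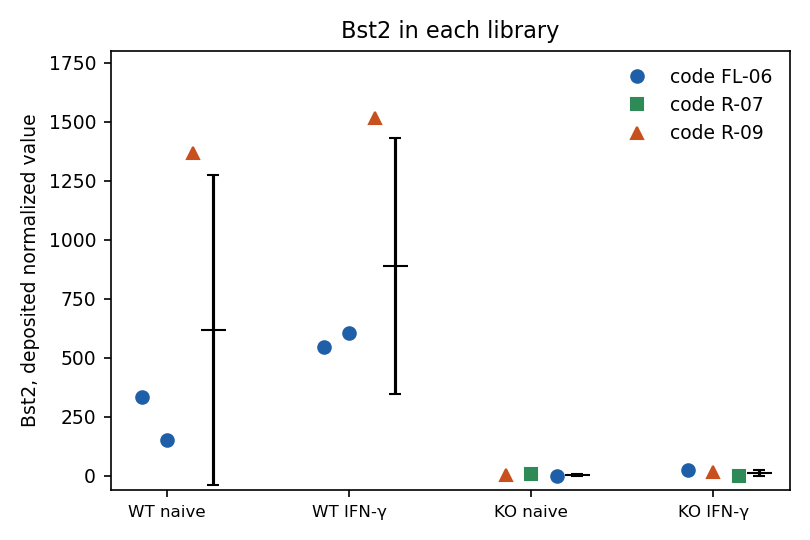
*Bst2* in each library, as the deposited normalized value on a linear axis, for the 4 groups, with points for libraries by code series and black marks for the mean ± SD of 3 libraries. All 6 KO libraries lie at or below 24.8 units and all 6 WT libraries at or above 152 units.

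The first comparison asked what 24 h of IFN-γ changed in WT HSCs. *Cd74*, the invariant chain of MHC class II, rose 5.86-fold (log2 fold change 2.55, SE 0.30, limma adjusted p = 0.03547), from 1544 ± 1728 to 6405 ± 3349 units (SD, n = 3 each). The large SDs include the difference between code series. *Cd74* was the only gene past the threshold of 10816 tested, and 804 genes had an unadjusted p below 0.05 against 541 expected by chance. No gene passed without the code series, with the replicate block or in 9 of the 12 fits without 1 library, and 15 passed without WT naive 3 and 2 without WT IFN-γ 3. Within each genotype the naive and treated libraries are balanced over the code series. Leaving out that covariate therefore cannot change the estimate of a treatment effect, and the log2 fold change of *Cd74* stayed at 2.55. The median log2 fold change of all genes was 0.11, and 0.02 after quantile normalization. The list tests compare a list with the other genes and so are relative to this shift.

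The antigen presentation and interferon lists rose together in WT HSCs. The MHC class II list had a median log2 fold change of 2.08 over 12 tested genes, all 12 of them above 0 (camera adjusted p = 1.154e-09), and a median of 0.83 after quantile normalization. Its members include *H2-Ab1* and *H2-Aa*, which encode chains of the class II molecule, and *Ciita*, the master activator of class II genes. The MHC class I list had a median of 0.57 over 22 genes, 21 above 0 (adjusted p = 3.18e-13). Type I interferon-stimulated genes had a median of 0.69 over 43 genes, 39 above 0 (adjusted p = 6.787e-10). The IFN-γ response list had a median of 0.55 over 36 genes, 30 above 0 (adjusted p = 6.97e-05). With an estimated correlation no list passed in WT (adjusted p = 0.33 for the first 3 lists and 0.44 for the IFN-γ response). In fry, which tests whether a list moves in 1 direction without comparing it with other genes, both MHC lists passed (adjusted p = 0.04919 each), and interferon-stimulated genes (0.07284) and the IFN-γ response (0.1243) did not. Adjusted over the list alone, 6 MHC class II, 12 MHC class I, 13 interferon-stimulated and 2 IFN-γ response genes rose, against 1, 0, 0 and 0 over all genes tested. Among these, *H2-K1*, a classical class I heavy chain, rose 1.59-fold, and *Tap1*, a subunit of the peptide transporter, rose 1.85-fold. *Oas3*, an antiviral RNA sensor, rose 3.54-fold and *Gbp3*, a guanylate-binding protein, rose 2.48-fold. Adjusted over all genes tested, these 4 genes had p between 0.0605 and 0.5235.

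**Figure D2:**
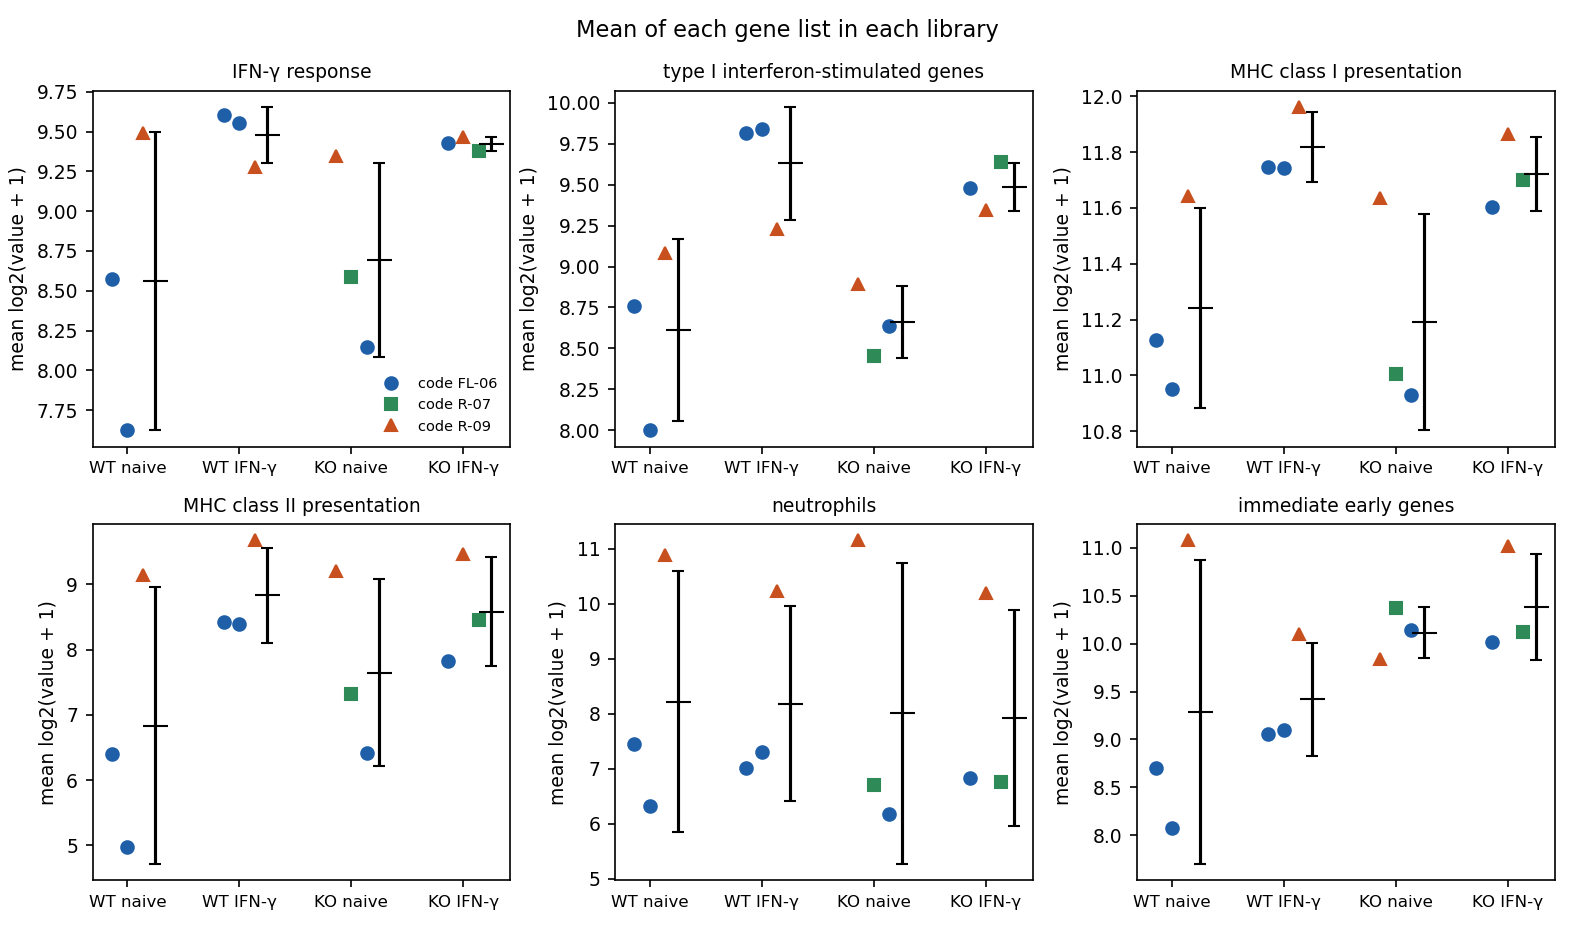
Mean log2(value + 1) of 6 gene lists in each of the 12 libraries, by group, with points for libraries by code series and black marks for the mean ± SD of 3 libraries. The R-09 libraries lie highest in the neutrophil panel (10.2 to 11.2, against 6.16 to 7.45 elsewhere), and the MHC class II mean was higher after IFN-γ in each of the 5 combinations of genotype and code series.

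Of the other groups in WT HSCs, megakaryocyte priming genes rose, with a median of 0.27 over 24 genes, 19 above 0 (adjusted p = 0.005316). Of these, 5 rose when adjusted over the list alone and 0 over all genes tested. They were *Itga2b*, the platelet integrin CD41 (1.56-fold), *Gp5*, a platelet glycoprotein (2.14-fold), *Plek* (1.55-fold), *Rab27b* (1.70-fold) and *F2r*, a thrombin receptor (1.32-fold). The G1/S list (median 0.17, 34 of 40 above 0, adjusted p = 0.001839) and the G2/M list (median 0.28, 29 of 35 above 0, adjusted p = 0.002487) also rose. None of their members passed on either adjustment. *Mcm6*, part of the replicative helicase and the G1/S gene of highest mean, had a log2 fold change of 0.14 (SE 0.10). The neutrophil list fell with a median of −0.48 over 20 genes, 6 above 0 (adjusted p = 3.414e-05), although its mean was −0.03. Immediate early genes tested lower than other genes (adjusted p = 0.01623), with a median of −0.14 and a mean of 0.13, so the mean had the opposite sign. With an estimated correlation the adjusted p was 0.33 for the megakaryocyte, G1/S, G2/M and neutrophil lists and 0.78 for immediate early genes. Of these 5 lists fry passed megakaryocyte priming (adjusted p = 0.04919), with 0.05005 for G2/M, 0.07631 for G1/S, 0.3746 for neutrophils and 0.8522 for immediate early genes. Within FL-06 and R-09 the medians were 0.30 and 0.20 for megakaryocyte priming, 0.17 and 0.25 for G1/S, 0.18 and 0.45 for G2/M and −0.27 and −0.75 for neutrophils. For immediate early genes they were 0.20 and −0.88, opposite in sign. Without WT naive 2 the FL-06 median was 0.49 for megakaryocyte priming and 0.13 for immediate early genes. Without the code series 5 lists passed in WT in place of 9.

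In *Bst2* KO HSCs the same 4 interferon and MHC lists rose after IFN-γ. The medians were 1.06 for MHC class II (10 of 12 above 0, adjusted p = 2.25e-08), 0.51 for MHC class I (21 of 22, adjusted p = 5.787e-23), 0.61 for type I interferon-stimulated genes (40 of 43, adjusted p = 1.989e-22) and 0.67 for the IFN-γ response (31 of 36, adjusted p = 2.331e-10). With an estimated correlation the adjusted p-values were 0.28, 0.15, 0.18 and 0.28 in the same order. None of these lists passed fry in KO (adjusted p = 0.3936, 0.09434, 0.2473 and 0.4364). No single gene passed over all genes tested (smallest limma adjusted p = 0.1641). Only 318 genes had an unadjusted p below 0.05, fewer than the 541 expected by chance. Adjusted over the list alone, 4 MHC class II, 11 MHC class I, 7 interferon-stimulated and 2 IFN-γ response genes rose. Examples are *H2-Eb1*, a class II chain (4.87-fold, from 311 ± 246 to 1241 ± 94.8 units, SD, n = 3 each), *H2-T22*, a non-classical class I gene (3.20-fold), *Cd74* (3.43-fold) and *Irf7*, a transcription factor of the interferon response (2.89-fold). *Tgtp1*, an interferon-inducible GTPase, rose 2.40-fold. The class I and GTPase genes have close paralogs, and the counting can have split reads between them. The neutrophil list fell (median −0.57, mean −0.08, 9 of 20 above 0, adjusted p = 0.0002306), as did the erythroid list (median −0.18, 3 of 18 above 0, adjusted p = 0.002174). Their adjusted p was 0.70 and 0.74 with an estimated correlation. Within FL-06, R-07 and R-09 the medians were −0.003, −0.32 and −1.15 for neutrophils. For the erythroid list they were 0.006, 0.10 and −0.74, so the fall did not hold within FL-06 and R-07. Without WT naive 2, 7 single genes passed in KO in place of 0.

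Averaged over both genotypes, a comparison added after the data were seen, 7 genes rose and 0 fell. These were *Cd74* (4.48-fold, limma adjusted p = 0.004041), *H2-Eb1* (4.55-fold, adjusted p = 0.01019), *H2-Ab1* (2.72-fold, adjusted p = 0.00654), *H2-T22* (2.65-fold, adjusted p = 0.01129), *Gbp3* (2.10-fold, adjusted p = 0.02959), *Tap1* (1.81-fold, adjusted p = 0.004041) and *H2-K1* (1.51-fold, adjusted p = 0.004041). All 7 belong to the interferon and MHC lists. All 4 lists passed in the average (camera adjusted p = 3.002e-12 for MHC class II, 3.912e-24 for MHC class I, 2.125e-22 for interferon-stimulated genes and 1.22e-10 for the IFN-γ response). Their adjusted p-values were 0.16, 0.13, 0.16 and 0.27 with an estimated correlation. In fry the first 3 passed (adjusted p = 0.02684, 0.01225 and 0.02684) and the IFN-γ response did not (0.0879). No single gene passed without the code series. The count was 22 without WT naive 2, the shallowest library, 15 without KO naive 1 and 13 without WT naive 3, and it was 3 without KO IFN-γ 1 and 4 without WT IFN-γ 1, KO naive 2 or KO IFN-γ 3. Adjusted over the list alone, 13 IFN-γ response, 22 interferon-stimulated, 16 MHC class I and 7 MHC class II genes rose. *Mcm3*, *E2f1* and *Mcm2* of the G1/S list also rose on that adjustment, by 1.26-fold, 1.61-fold and 1.17-fold.

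**Figure D3:**
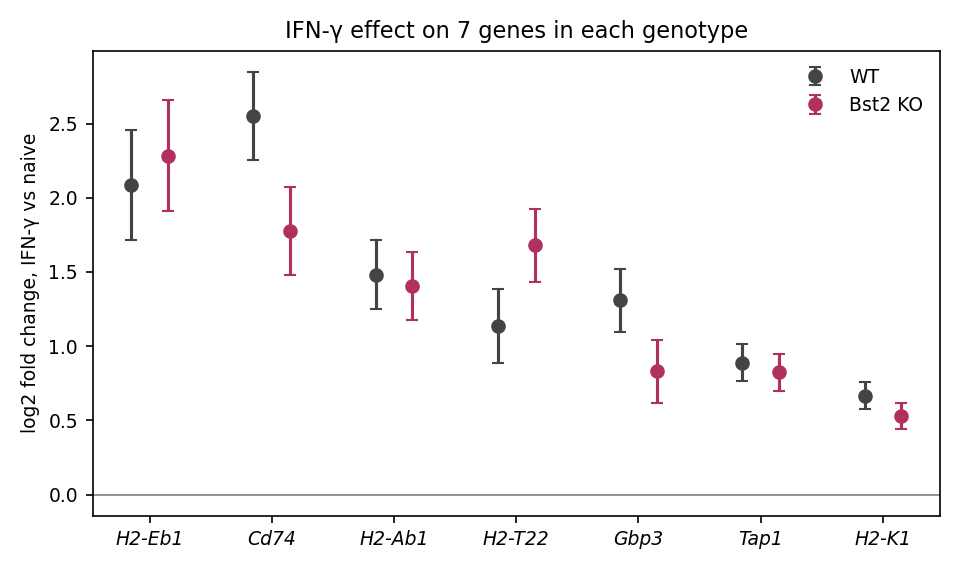
Log2 fold change (IFN-γ against naive) of 7 genes in WT and in *Bst2* KO HSCs, with bars of ± 1 SE from the model of 12 libraries. The genes were chosen for passing the threshold in the average over both genotypes, so their rise is given by the choice, and all 14 values lie above 0, from 0.53 for *H2-K1* in KO to 2.55 for *Cd74* in WT.

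The neutrophil genes fell in the average as well (median −0.53, mean −0.06, 7 of 20 above 0, camera adjusted p = 2.18e-07, and adjusted p = 0.30 with an estimated correlation). Of the list, 9 genes fell when adjusted over the list alone. They included *Ngp*, a neutrophil granule protein (0.58-fold), *S100a9* (0.58-fold) and *S100a8* (0.55-fold), which form calprotectin, and *Ltf*, lactoferrin (0.66-fold). These genes followed the code series: *S100a8* lay between 11818 and 38198 units in the 4 R-09 libraries and between 195 and 810 units in the other 8. Without the code series in the model the list did not pass (camera adjusted p = 0.1154), with a median of −0.53 that the balanced design keeps the same. The G1/S (adjusted p = 0.001251) and G2/M lists (adjusted p = 0.02996) rose and the erythroid list tested lower than other genes (median −0.07, 7 of 18 above 0, adjusted p = 0.007669), with adjusted p of 0.38, 0.38 and 0.57 with an estimated correlation. Within code series the erythroid medians in WT were 0.01 in FL-06 (−0.22 without WT naive 2) and −0.01 in R-09, and of the 3 KO medians given above only that of R-09 was negative. In KO the medians in FL-06, R-07 and R-09 were 0.17, 0.07 and −0.03 for G1/S and 0.10, 0.11 and −0.09 for G2/M.

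The IFN-γ effect was also read within each code series. In WT the median of the MHC class II list was 2.46 in FL-06 and 0.46 in R-09. In KO it was 1.45 in FL-06, 1.14 in R-07 and 0.43 in R-09. Type I interferon-stimulated genes had medians of 1.10 and 0.16 in WT (FL-06, R-09), and of 0.82, 0.76 and 0.32 in KO (FL-06, R-07, R-09). For MHC class I these were 0.70 and 0.24 in WT, and 0.69, 0.68 and 0.18 in KO. For the IFN-γ response they were 0.81 and 0.05 in WT, and 1.04, 0.72 and 0.09 in KO. All 5 combinations had a positive median for each of these lists. Without the shallow library WT naive 2 the WT medians in FL-06 were 0.69 for interferon-stimulated genes, 1.65 for MHC class II, 0.70 for MHC class I and 0.67 for the IFN-γ response. When treatment labels were permuted within genotype and code series, the mean of the MHC class I, MHC class II and interferon-stimulated lists gave p = 0.02083 in an exact permutation test. This is the smallest p that 96 arrangements allow, and the adjusted p over the lists was 0.1208. Markers of other cell types gave the same p in this exact test, with list means higher in all 5 combinations and mean differences of 0.859 for mature B and plasma cells (5 genes) and 0.868 for mature T and NK cells (3 genes). The medians did not follow for B and plasma cells, at −0.31 (−0.44 without WT naive 2) and 0.21 in WT (FL-06, R-09) and 0, 0 and 0.03 in KO (FL-06, R-07, R-09). In KO 2 of the 5 genes were above 0, with *Igll1* at a log2 fold change of 3.91, and with a pseudocount of 10 the mean rose in 4 of 5 combinations (exact permutation p = 0.1042). For T and NK cells the medians were 1.60 (0.19 without WT naive 2) and 0.22 in WT and 1.01, 0.88 and −0.06 in KO. The mean differences were 0.524 for MHC class I, 0.816 for interferon-stimulated genes and 1.21 for MHC class II. The IFN-γ response list, whose mean rose in 4 of the 5 combinations, gave p = 0.0625 in the same exact test. Over its 23 members of at least 100 in all 12 libraries, a minimum added after the data were seen, the mean rose in all 5 combinations (exact permutation p = 0.02083, adjusted p = 0.1042). At that minimum the B and plasma cell list and the T and NK cell list had fewer than 3 members and were not tested.

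The interaction asked whether the IFN-γ effect differed between genotypes, and none of the 4 interferon and MHC lists passed it. The median difference, KO minus WT, was −0.15 for the IFN-γ response (adjusted p = 0.88), 0.05 for interferon-stimulated genes (0.59), −0.05 for MHC class I (0.89) and −0.64 for MHC class II (0.30). Interferon-stimulated genes had a mean of −0.19, opposite in sign to their median. The tests of the IFN-γ response and MHC class I pointed up against negative medians, and the median of all genes was −0.11. The adjusted p was 0.98 with an estimated correlation for each of the 4 lists. Without WT IFN-γ 3 the MHC class II list passed (median −1.01, adjusted p = 0.0289). No gene passed either (367 at an unadjusted p below 0.05, smallest limma adjusted p = 0.9331). For *Cd74* the difference was −0.77 on the log2 scale, with an SE of 0.42. Of 113 genes on the 4 lists, 102 had a positive effect in WT, 102 in KO and 96 in both, against 62.2% and 51.0% of all genes in WT and KO. Across these 113 genes the effects in WT and KO correlated with Pearson r = 0.58 and Spearman rho = 0.56, and across all 10816 genes with r = 0.07 and rho = 0.08. Genes are not independent replicates, so no p is given.

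Outside the interferon lists, 3 lists passed the interaction. Megakaryocyte priming genes had a lower effect in KO than in WT (median difference −0.37, 2 of 24 above 0, adjusted p = 0.004232). *Plek* had a difference of −0.94 (SE 0.26) and *Gp5* of −1.29 (SE 0.40), and both missed the threshold (adjusted p = 0.93). The G2/M list was lower (median −0.26, 6 of 35 above 0, adjusted p = 0.03334) and immediate early genes were higher (median 0.28, 17 of 24 above 0, adjusted p = 0.01579). The adjusted p-values were 0.75, 0.88 and 0.98 with an estimated correlation. No list passed fry in the interaction (smallest adjusted p = 0.2847) or in the genotype differences (0.5017 in naive and 0.4887 in treated HSCs). Megakaryocyte priming did not pass without WT naive 1 (adjusted p = 0.08013), KO naive 2 (0.06215) or KO IFN-γ 3 (0.0619). The G2/M list did not pass in 8 of the 12 fits without 1 library (adjusted p from 0.0619 to 0.9903), without R-09 (0.9939), with no filter (0.05183), with the CPM filter (0.05139) or when rescaled without non-coding and haemoglobin genes (0.05695). For the immediate early genes the median turned to −0.34 without the R-09 libraries, −0.15 without WT naive 3 alone and −0.12 without KO naive 1 alone, and the list did not pass without WT IFN-γ 3 (0.05143) or KO IFN-γ 1 (0.188). Without the code series none of the lists passed (adjusted p = 0.2508, 0.1591 and 0.1378 in the order megakaryocyte, G2/M, immediate early). The 3 medians were unchanged, which the balanced design fixes in advance.

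Naive KO and WT HSCs were compared to ask what loss of *Bst2* changes without IFN-γ. No gene and none of the 29 lists passed (702 genes at an unadjusted p below 0.05, against 541 by chance). *Bst2* itself had a log2 fold change of −6.72 (SE 1.39, limma adjusted p = 0.71). Its log2 values had an SD of 2.06 over the 6 KO libraries and 1.25 over the 6 WT libraries. HSC identity genes had a median difference of 0.14 over 38 genes (adjusted p = 0.50) and niche adhesion genes of 0.18 over 39 genes (adjusted p = 0.33). Adjusted over the list alone, *Plek*, a platelet and leukocyte signalling protein, was 1.77-fold higher in KO. *Xbp1*, a transcription factor of plasma cells, was lower at 0.68-fold. *Igll1*, a pre-B-cell receptor component, was also lower, from 102 ± 31.4 units in WT to 5.04 ± 4.73 units in KO (SD, n = 3 each), close to the floor of detection. Without the R-09 libraries the immediate early genes passed, with a median of 1.12 (adjusted p = 6.178e-14) against 0.36 with all libraries (adjusted p = 0.29).

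In treated HSCs the immediate early genes, transcription factors induced within minutes of a stimulus, were higher in KO than in WT. The median log2 difference was 0.74 over 24 genes, 21 above 0 (camera adjusted p = 1.262e-13, and adjusted p = 0.44 with an estimated correlation). No member passed on its own. *Fos* had a 2.02-fold difference (SE 0.41 on the log2 scale) and *Jun* a 1.36-fold difference (SE 0.21). Megakaryocyte priming genes were lower (median −0.22, 3 of 24 above 0, adjusted p = 0.0008126). So were MHC class II (median −0.37, 3 of 12 above 0), oxidative phosphorylation (median −0.14, 8 of 30) and histone genes (median −0.30, 5 of 19), each with adjusted p = 0.04334. Markers of monocytes, macrophages and dendritic cells were lower (median −0.43, 1 of 15 above 0, adjusted p = 0.04535), and the quiescence list was higher (median 0.12, 17 of 28, adjusted p = 0.04334). With an estimated correlation these adjusted p-values lay between 0.44 and 0.57. Within FL-06 and R-09 the medians were −0.28 and −0.03 for megakaryocyte priming, −0.53 and −0.33 for MHC class II, −0.17 and −0.16 for oxidative phosphorylation, −0.25 and −0.23 for histones and −0.36 and −0.86 for monocyte markers. For quiescence they were −0.08 and 0.42, opposite in sign. Without the code series the megakaryocyte median was −0.11 and the list did not pass (adjusted p = 0.4719). *Mpo*, myeloperoxidase, was lower in KO at 0.72-fold when adjusted over its list alone. No gene passed over all genes tested (226 at an unadjusted p below 0.05, smallest limma adjusted p = 1).

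Immediate early genes differed between code series and libraries. In FL-06, with 1 KO and 2 WT libraries per condition, the KO minus WT median was 1.08 in naive and 0.92 in treated libraries (24 and 21 of 24 genes above 0). In R-09, with 1 library per group, it was −0.79 in naive and 0.77 in treated libraries (0 and 23 of 24 genes above 0). *Fos* ranged from 1454 to 5733 units in the 8 libraries outside R-09 and from 14594 to 33587 units in R-09.

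The remaining lists passed in neither genotype after IFN-γ. HSC identity genes had medians of 0.06 in WT and −0.04 in KO (camera adjusted p = 0.33 and 0.47), with *Gata2*, a stem cell transcription factor, at 0.07 (SE 0.17) and −0.03 (SE 0.17). Niche adhesion and homing genes had 0.14 and −0.05 (0.19 and 0.69). The quiescence list had 0.03 and −0.08 (0.18 and 0.35), the IFN-γ receptor list 0.08 and 0.26 (0.61 and 0.14), and NF-κB targets 0.25 and 0.10 (0.67 and 0.57). MYC and ribosome biogenesis genes had 0.12 and 0.02 (0.54 and 0.69), p53 targets 0.14 and −0.03 (0.85 and 0.69), and apoptosis genes 0.19 and 0.06 (0.89 and 0.83). Oxidative phosphorylation had 0.07 and 0.04 (0.63 and 0.95), glycolysis 0.22 and 0.01 (0.10 and 0.93), and the *Bst2* neighbours 0.26 and 0.13 (0.36 and 0.48). Histone genes had 0.22 in WT and −0.00032 in KO (0.67 and 0.95). Among lineage lists, myeloid priming had 0.31 and 0.03 (0.67 and 0.93) and lymphoid priming 0.14 and −0.09 (0.89 and 0.88). Cell markers had 0.89 and −0.81 for monocytes, macrophages and dendritic cells (0.67 and 0.24), and 0.53 and −0.07 for mast cells and basophils (0.36 and 0.69). The WT median of the monocyte list within FL-06 was 1.47, but 0.02 without the shallow library WT naive 2, and it was −0.27 in R-09. For T and NK cells they had 1.14 and 0.60 (3 genes, 0.26 and 0.48), for B and plasma cells 0.44 and −0.01 (5 genes, 0.67 and 0.35), and for endothelium and stroma −0.19 and −0.53 (7 genes, 0.67 in WT and 0.69 in KO). In WT the test pointed down against a positive median for HSC identity, quiescence, NF-κB, p53, myeloid and lymphoid priming, B and plasma cells and monocytes. Mean and median had opposite signs for endothelium and stroma in WT (mean 0.38), and in KO for myeloid priming (mean −0.09), lymphoid priming (mean 0.11), B and plasma cells (mean 1.07) and histones (mean 0.08).

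The genes of the sort gate describe the sort. *Kit* averaged 9365 ± 2328 units in WT naive, 7846 ± 1721 in WT treated, 9714 ± 1915 in KO naive and 8822 ± 487 in KO treated HSCs (SD, n = 3 each). *Slamf1*, which encodes CD150, averaged between 431 and 666 units. *Cd34* lay between 3098 and 3629 units in the R-09 libraries and between 462 and 821 units in the other 8. *Cd48* lay between 368 and 582 units in R-09 and between 1.08 and 268 units in the others.

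The R-09 libraries stood apart in both genotypes and treatments. The correlation of log2 values between libraries was 0.93 to 0.96 within R-09, 0.75 to 0.98 among the other 8 libraries and 0.41 to 0.57 between the 2 sets. Part of the difference followed transcript length: across 7289 genes, the log2 ratio of R-09 to the other libraries fell with the log2 length of the longest transcript (Pearson r = −0.55, Spearman rho = −0.57). The median ratio was 1.01 for transcripts of up to 2332 nt (the lower quartile) and −1.19 for those from 4792 nt (the upper quartile). Of 20 RNAs that lack a poly(A) tail, among them *Rn45s* and *Rpph1*, 20 were lower in R-09, with a summed mean of 987 against 372034 units. *Mki67*, a proliferation gene with a long transcript, lay between 332 and 630 units in R-09 and between 17574 and 24051 units elsewhere. Lists of cell markers also differed. The mean log2 value of myeloid priming genes was 9.52 to 9.91 in R-09 and 6.11 to 7.43 elsewhere. For monocytes, macrophages and dendritic cells it was 9.01 to 10.2 and 4.68 to 6.96. The erythroid list and the endothelium and stroma list overlapped between the 2 sets. These means were not corrected for transcript length, and whether R-09 held other cells was not tested. Each treatment comparison within a genotype had 1 R-09 library on each side.

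**Figure D4:**
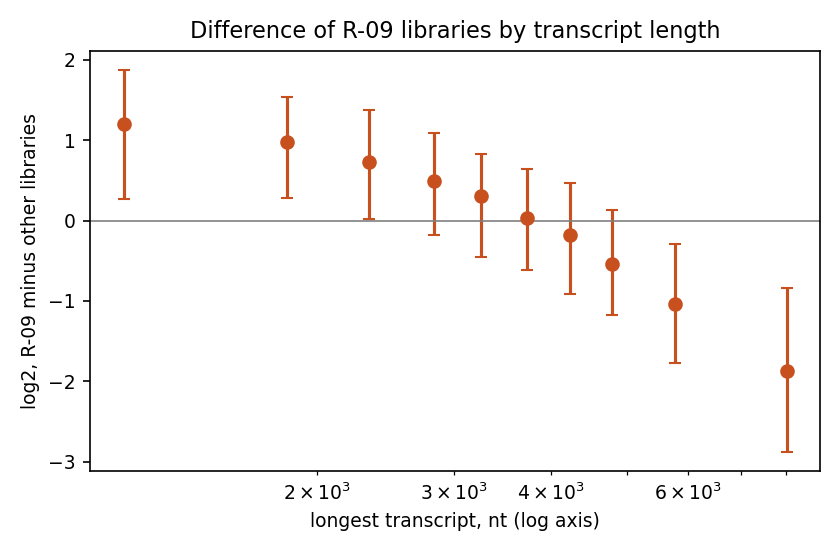
Log2 ratio of the mean of the 4 R-09 libraries to that of the other 8, for 10 bins of genes by longest transcript (x axis in nt, log scale), with points for medians and bars for the quartiles over 728 or 729 genes per bin. The median falls from 1.21 in the bin with the shortest transcripts to −1.88 in the bin with the longest.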

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

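The tests of a treatment effect that differs between code series, all 8 tests of explanations and the splits within genotype and code series were chosen after the results were seen, and the other splits of the libraries were planned. In the patterns below, each SE beside a median is the SE of the mean over genes. It treats genes as independent and does not measure the spread between libraries.

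The IFN-γ effect differed between genotypes for 3 lists in the interaction test: megakaryocyte priming genes (median difference KO minus WT −0.37), immediate early genes (0.28) and G2/M genes (−0.26). None of the 3 passed with an estimated correlation (adjusted p = 0.75, 0.98 and 0.88). It differed between R-09 and the other code series for 7 lists (camera on a treatment by R-09 term, 0 single genes past the limma threshold and 434 at an unadjusted p below 0.05). The median difference, R-09 minus the others, was −0.89 for the IFN-γ response (adjusted p = 4.133e-10), −0.85 for interferon-stimulated genes (1.09e-09), −0.35 for MHC class I (9.424e-09) and −1.24 for MHC class II (3.457e-07). It was −0.80 for neutrophils (0.0005669), −0.32 for erythroid genes (0.02695) and −1.58 for monocytes, macrophages and dendritic cells (0.03013). For the monocyte list the WT median within FL-06 was 1.47, but 0.02 without the shallow library WT naive 2. With an estimated correlation the IFN-γ response (adjusted p = 0.04726) and MHC class I (0.03185) still passed, and the adjusted p was 0.08187 for interferon-stimulated genes and MHC class II, 0.3293 for neutrophils, 0.6244 for erythroid genes and 0.2039 for monocytes.

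The first pattern is the smaller rise of the interferon and MHC lists in R-09. Low values and shallow libraries were checked on 80 members of at least 100 units in all 12 libraries. The effect outside R-09 exceeded that in R-09 by a median of 0.59 (SE over genes 0.058), in 72 of 80. At 1 read per step that minimum is worth about 3 reads in WT naive 2, and each R-09 effect compares 1 library with 1. This explanation is therefore not excluded. In KO, without WT naive 2, the median of each interferon and MHC list was also higher in FL-06 and R-07 than in R-09. The SD across genes in R-09 was 0.968 times that of the other libraries, so the spread of values between genes was not clearly smaller. This SD includes the trend with transcript length and does not measure treatment effects, so a compression of effects in R-09 stays open. Also open is a higher interferon signal in the naive R-09 libraries. These members lay 0.56 (SE 0.15) above the other naive libraries there, after correction for the longest transcript length. Random lists lay between −0.21 and 0.42 (outer percentiles, 2.5 at each end). With the median transcript length the value was 0.77 (SE 0.17). The treated R-09 libraries lay at −0.09 (SE 0.14) against the other treated libraries, after correction for the longest transcript length. The value in the naive libraries depends on the correction and cannot be told apart from what else sets the R-09 libraries apart. They differ by transcript length and hold little RNA without a poly(A) tail, although the labels name a total RNA kit. Their neutrophil, myeloid priming and monocyte list means were also higher. The labels do not say what a code series is, so no cause of a higher signal was tested.

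The second pattern is the lower neutrophil genes after IFN-γ. The mean of the whole list did not pass the permutation within genotype and code series (−0.123, exact permutation p = 0.7083), and that of the 11 members of at least 100 in all 12 libraries was −0.55 (p = 0.02083, adjusted p = 0.1042). Fewer mature neutrophils, or less of their RNA, in the treated samples stays open, although the gate excluded lineage-positive cells. The 11 members of at least 1000 units in both naive R-09 libraries had a median of −1.09 (SE over genes 0.084) in the R-09 pairs, against −0.09 (SE 0.095) for 9 myeloid priming genes chosen in the same way, with 2 genes on both lists left out. These members were chosen on the naive side, the pairs hold 1 library on each side, and the fall was seen before the test, so the values decide nothing. Whether the change belongs to R-09 alone also stays open: outside R-09 the same members had a median of −0.45 (SE 0.26), 9 of 11 were lower, and 6 were lower in all 5 pairs. An IFN-γ effect on these genes within HSCs also stays open and was not tested.

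The third pattern is the higher immediate early genes in KO. A difference between code series stays open: within FL-06 the median difference was 1.08 (SE over genes 0.36) in naive and 0.92 (SE 0.14) in treated libraries, but FL-06 holds 1 KO library in each condition. A steady genotype difference in all code series was not seen in the naive R-09 pair, at −0.79 (SE 0.23), with 0 of 24 genes higher in KO. The treated R-09 pair gave 0.77 (SE 0.17), with 23 of 24 higher. With 1 library on each side, these pairs cannot decide it, and it stays open. Handling time before lysis may also move these genes, and the naive and treated WT libraries of R-09 differed by 0.98 in the list mean, but no label gives a time.

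Other splits of the libraries gave these counts. For 3 against 3 libraries there are 10 splits, too few for a share under 0.05. The real and the highest other number of genes were 1 and 1 in WT (3 splits with a count as large), 0 and 5 in KO (10), 0 and 1 for the naive genotype difference (10) and 0 and 1 for the treated genotype difference (10). For lists they were 9 and 7 in WT (1), 6 and 12 in KO (4), 0 and 9 for the naive (10) and 7 and 9 for the treated genotype difference (4). For the interaction, the highest other number of genes in 100 splits was 19, against 0 in the real split. Every split reaches a real count of 0, so the gene counts of the interaction, KO and both genotype differences decide nothing. Of the 100 splits for the interaction, 55 gave as many lists (3, highest other 12), so chance is not excluded for the lists. For the average over both genotypes 5 of 100 splits gave as many genes (7, highest other 857) and 11 as many lists (8, highest other 12), so chance is not excluded there either. A split with 857 genes points to a structure of the samples. When treatment was split only within genotype and code series, the real split alone of 48 reached 7 genes (highest other 0). This is the smallest share that scheme allows. The wider splits, with 5 of 100 as large, also exchange libraries between code series and so are not a like measure. Both the scheme and the average were chosen after the data were seen. Chance is therefore not excluded for these genes. For lists, 11 of 48 reached 8 (highest other 11), so chance is not excluded for them either.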

How the results depend on the processing

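Quantile normalization, rescaling, library weights, leaving out R-09 and the minimum of 100 in all 12 libraries were chosen after the data were seen, as was the average over both genotypes, and the other settings were planned. Of the values under alternatives, without the counts, correlation and *Bst2* ratio given below, 12869 were classed as the same. A further 134 gained a call, 77 lost it, 9 moved and 3 reversed. The class of the same includes sign changes of values that did not pass in the main fit. The cause of the changes below was not tested unless stated. Tests on whole counts (another size factor, a Wald test, leaving gene classes out before scaling) were not run, because the values are not counts. WT naive 2, at an estimated 0.495 M reads, limits calls of genes below about 102 units.

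Counts are of genes unless lists are named, with the main counts being WT 1, KO 0, naive difference 0, treated difference 0, interaction 0 and average 7 genes, and 9, 6, 0, 7, 3 and 8 lists. With a pseudocount of 0.1 WT had 0 and the treated difference 3 lists, and with 10 WT had 5 and the average 13. No filter gave WT 2. Without the code series WT had 0 and 5 lists, the treated difference 4 lists, the interaction 0 lists and the average 0 and 4 lists. With only the groups compared WT had 0, KO 4 and the treated difference 1 (*Amd1*, which has a near-identical copy). Quantile normalization gave WT 4, KO 7, the average 29, the naive difference 1 list and the treated difference 4 lists. Library weights gave WT 9, KO 7, the average 42 and the naive difference 4 lists. Without R-09 WT had 2, KO 10 lists, the naive difference 4 lists, the treated difference 2 and 3 lists, the interaction 1 and 1 list, and the immediate early interaction reversed to −0.34. A minimum of 100 in all 12 libraries, with 7320 genes tested, gave WT 7, KO 6, the average 34, the naive difference 1 list, the treated difference 3 lists and a correlation of WT and KO effects of 0.17. All 7 genes of the average were shared under the pseudocount of 10, quantile normalization, weights and this minimum, and 5 without R-09.

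With the replicate block in place of the code series WT had 0 and 4 lists, the treated difference 4 lists, the interaction 0 lists and the average 0 and 4 lists. The replicate block with the code series gave WT 0 and the naive difference 1 list. Same-numbered WT libraries share a code series and correlated at 0.55, 0.46 and 0.83, but at 0.14, −0.34 and −0.55 once the series was removed (KO 0.04, 0.21 and 0.44), so the numbers were not taken to pair samples.

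Leaving out 1 library at a time gave WT 0 to 15, KO 0 to 7, naive difference 0 to 3, treated difference 0 to 1, interaction 0 to 2 and average 3 to 22. Lists ranged over 6 to 11, 5 to 9, 0 to 7, 2 to 12, 1 to 4 and 6 to 10 in the same order, the correlation over −0.11 to 0.24 and the *Bst2* ratio over 64.3 to 120. The highest gene counts came without WT naive 3 (WT, naive difference, interaction) and WT naive 2 (KO, average). Without WT naive 3 and without KO naive 1 the immediate early interaction reversed to −0.15 and −0.12 (its highest value was 0.53), and in the naive difference that list passed at 0.94 and 0.70.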

Other observations

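No hypothesis was tested here, and the values below were chosen after they were seen.

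A few genes outside the groups described above passed in the average over both genotypes when adjusted over their list alone, and none of them over all genes tested. *Vcam1*, an adhesion molecule of macrophages and stroma, fell after IFN-γ (log2 fold change −1.37, SE 0.34, limma adjusted p = 0.3559), as did *Txnip*, an inhibitor of thioredoxin (−0.36, SE 0.08, limma adjusted p = 0.2146). They were the only such members of the monocyte and the quiescence list. *Malat1*, a nuclear non-coding RNA, had a log2 fold change of −0.75 (SE 0.15, limma adjusted p = 0.347) in WT, and it passed in WT under quantile normalization, library weights and the minimum of 100 in all 12 libraries.

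*Xist*, the RNA of the inactive X chromosome, lay between 172 and 264 units in the 4 R-09 libraries and between 10662 and 20760 units in the other 8, while the Y-linked gene *Ddx3y* lay between 306 and 608 units in all 12. Both were above 0 in all 12 libraries. The R-09 libraries were low in long transcripts in general and the labels do not tie libraries to mice, so no sex was read from these values. *Rn45s*, the ribosomal RNA precursor, took 2.15 to 2.66% of the total in the 2 R-07 libraries, 0.243 to 0.375% in the 6 FL-06 libraries and at most 0.000692% in the 4 R-09 libraries.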
